A study of Mus musculus with 10 samples.

How the data were processed

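Each of the 10 arrays (Affymetrix Mouse430_2) held a pool of hippocampal RNA from 3 to 4 mice, in 5 groups of 2 arrays, per the labels. The deposited values are intensity, as the MAS5 signal of each probe set on a linear scale, and per the submitters' processing notes they were made with MAS5 in GCOS, whose versions and background settings are not given in the sources used here. Checked on the values, no signal was negative, the highest was 38807.9 and the 2% trimmed mean of each array lay between 500.002 and 500.003, so that each array had been scaled to a common mean. The median signal ran from 94.5 to 106 on arrays numbered 1 and from 134 to 152 on those numbered 2. The 3' to 5' signal ratio ran from 1.34 to 1.69 for actin and from 0.723 to 0.824 for Gapdh.

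Of 45101 probe sets, 64 controls were left out, 34945 named 1 gene, 932 named several genes and 9160 named none, in a table of probe sets and genes for this platform. List members written under an older symbol were matched through the synonyms of the reference annotation (GRCm38.p6), and members with no probe set of their own were not analysed here. Signals were taken as log2(signal + 22), where 22 is the 20th percentile of all signals, with no further scaling since the trimmed means were equal. That equality came from the deposited scaling and does not show like distributions, since the median signals differed between the replicate numbers. The pseudocount lowers the fold of genes that are dim in a group. A probe set was tested where its mean over the 10 arrays ranked in the upper 60%, which left 27023 probe sets, 23684 of them with 1 gene. A gene was represented by its probe set with the highest mean, giving 13219 genes, of which 6173 had several tested probe sets. No named gene had another tested probe set past the threshold in the opposite direction.

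All arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend), with 5 residual degrees of freedom. Tests were two-sided, Benjamini-Hochberg adjusted within each of 9 comparisons, with a threshold of 0.05 on the adjusted p. The comparisons were the kainate response in wild type at 14 mg/kg and in A-CREB at 14 and 18 mg/kg, the basal genotype difference, the differences between the responses, the genotype differences after kainate and the difference between the doses. The replicate number entered as a block in a stated alternative (4 residual degrees of freedom). The labels do not say what the numbers mark, but all 10 arrays correlated best with an array of the same number, 4618 genes differed between the numbers and the numbers separated on the first principal component (46.0% of the variance).

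The groups, tests, gene lists and most alternatives were chosen before the data were examined. The genes named for a comparison are the 14 with the largest rise and the 10 with the largest fall among those past the threshold whose arrays do not overlap between the groups, up to 4 members of each list by smallest p, and Creb1. There were 30 gene lists. Of these 28 had at least 3 measured members and were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Of 93 calls with the preset correlation 17 also passed with an estimated correlation, and with the replicate block the numbers were 93 and 3. The blood cell list had 2 of 7 and the sex-linked list 1 of 5 members measured, so neither was tested. Response size was the least-squares slope through 0 of the A-CREB on the wild-type response, with pairs of same-numbered arrays as the replicates and an exact permutation test. Creb1 probe sets were compared by an exact permutation test over the 100 arrangements within the replicate numbers.

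The procedure was tested on simulated data of the size of the wild-type comparison, with 200 of 13219 genes changed in each of 5 runs. It found 16.2% of genes changed by a log2 of 1 and 75.6% of those changed by 2, with 0 false calls per run. With the replicate block it found 78.6% and 99.6%, with 15.2 false calls per run. The simulated data took the difference between the numbers and the noise from the blocked fit, alike in every group. The gain with the block was thus built in. In another simulation, of the basal genotype difference without the block, 5 lists were shifted by 0.5 with independent noise. Of these 5 were found with either correlation, and 0 of the 21 lists without shifted members were called. Since the noise was independent between genes, this simulation did not test for false calls from list members that vary together. Alternatives were a smaller pseudocount and one 4 times larger, no filter and the upper 40%, quantile and cyclic loess normalization, no intensity trend, robust variance, array weights, the mean of a gene's probe sets, no probe sets ending in _s_at, _x_at or _a_at, only the groups of a comparison, a fold threshold, the replicate block and leaving out each array. Added after the data were seen were leaving out arrays within the block, the block with quantile normalization, the block with the striatum and choroid plexus scores as covariates, the genotype difference averaged over saline and 14 mg/kg, the exchange of arrays within replicate numbers for Creb1, and the ratio of mean responses. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.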

Results

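Hippocampal RNA of 3-week-old mice was measured on 10 oligonucleotide arrays, each with 45101 probe sets. The mice were wild type or carried A-CREB, a dominant-negative inhibitor of CREB, the cAMP-responsive transcription factor, under a tetracycline-controlled promoter. They received saline or kainate, a glutamate receptor agonist that provokes seizures. There were 5 groups of 2 arrays, named replicate 1 and replicate 2 in the labels: wild-type saline, wild-type kainate at 14 mg/kg, A-CREB saline, A-CREB kainate at 14 mg/kg and A-CREB kainate at 18 mg/kg. No wild-type group received 18 mg/kg, and the interval between injection and dissection is not given in the sources used here. In all, 14 wild-type and 20 A-CREB mice entered the pools, and each array held RNA of 3 to 4 mice, so errors and p-values measure the spread between pools and not between single mice. In fits without the replicate block that spread also holds the difference between the replicate numbers, between which 4618 genes differed. The median signal ran from 94.5 to 106 on the arrays numbered 1 and from 134 to 152 on those numbered 2, and the number of arrays limits the precision of every value below. Changes are log2 differences of group means with the standard error of the limma fit and n = 2 arrays per group, over 13219 genes.

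The response of wild-type mice to 14 mg/kg kainate was led by Npas4, an activity-dependent transcription factor, which rose 46.3-fold (log2 5.53, SE 0.27, adjusted p = 2.83e-05). Its deposited signal was 210 ± 57.6 (SD, n = 2) after saline and 10580 ± 670 after kainate. Fos, a subunit of the AP-1 transcription factor, rose by 3.26 (SE 0.22, adjusted p = 0.000237), from a signal of 1855 ± 619 to 17456 ± 1448. Atf3, a stress-induced transcription factor, rose by 4.62 (SE 0.41, adjusted p = 0.00194). Its signals after saline, 29.7 and 47.7, were near the pseudocount of 22, so the size depends on it (5.07 with a pseudocount of 5.5 and 3.61 with 88). Ptgs2, the inducible enzyme of prostaglandin synthesis, rose by 3.45 (SE 0.35, adjusted p = 0.00441). Bdnf, a neurotrophin, rose by 2.22 (SE 0.24, adjusted p = 0.00553). Npas4 lies on chromosome 19 from 4984353 to 5003439 and Fos on chromosome 12 from 85473890 to 85477274 in mouse assembly GRCm38.p6. The AP-1 subunit Fosb rose by 3.88, Cenpa, a histone variant of centromeres, by 2.84, and the stress-response genes Gadd45b and Gadd45g by 2.64 and 2.42. Gem, a small GTPase that restrains calcium channels, rose by 2.33, the transcription factor Csrnp1 by 2.26, Errfi1, a feedback inhibitor of the EGF receptor, by 2.16, the Ras-like gene Rasl11a by 2.06 and Rgs2, a regulator of G-protein signalling, by 2.05. In all, 24 genes rose and 0 fell by limma, with 466 genes at an unadjusted p under 0.05 against 661 expected by chance. With the replicate number as a block, 82 rose and 12 fell, with 1289 genes at an unadjusted p under 0.05. The count was 15 without wild-type saline replicate 1, 5 without wild-type saline replicate 2, 5 without wild-type kainate replicate 1 and 13 without wild-type kainate replicate 2. These fits had no block, so without an array of either group the difference between the replicate numbers also entered the comparison. Npas4, Fos, Atf3 and Cenpa passed whichever array was left out. Of the 14 genes named, 10 missed the threshold without wild-type kainate replicate 1 (adjusted p from 0.0645 to 0.462), 10 without wild-type saline replicate 2 (0.0531 to 0.450). Without wild-type kainate replicate 2 there were 5 (0.0510 to 0.172) and 4 without wild-type saline replicate 1 (0.0739 to 0.260). Gem, Gadd45g and Rasl11a also missed it without either A-CREB array at 14 mg/kg (highest adjusted p 0.0838), and Gadd45g and Rasl11a without either A-CREB saline array (highest 0.0912). With all arrays, 6 of the 14 missed it without an intensity trend (0.0542 to 0.161) and Gadd45g, Gem and Rasl11a with no filter (highest 0.0695). Gem, also dim after saline, was at 1.71 with a pseudocount of 88.

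Among the fixed gene lists, immediate-early transcription factors rose as a group in wild-type mice, with a median change of 1.75 over 25 genes (camera adjusted p = 4.43e-68, and adjusted p = 0.0184 with an estimated correlation). Over all genes 8 members rose and 17 did not pass, 22 rose adjusted over the list alone, and 19 rose over all genes with the replicate block, where the adjusted p with an estimated correlation was 0.065. Npas4, Fos, Atf3 and Csrnp1 had the smallest p. Of 36 activity-regulated effectors, which act at synapses and in signalling, 9 rose and 27 did not pass (median 1.33, adjusted p = 2.91e-66, and 0.0193 as adjusted p with an estimated correlation). The count was 28 adjusted over the list alone and 20 with the block, with which the adjusted p was 0.0698 with an estimated correlation, and the examples were Ptgs2, Bdnf, Errfi1 and Rgs2. Of 29 CREB target genes 4 rose and 25 did not pass, 19 adjusted over the list alone and 15 with the block: Fos, Bdnf, Gadd45b and the nuclear receptor Nr4a2 at 1.89 (SE 0.28). Their median was 0.97 (adjusted p = 2.18e-42, adjusted p = 0.0184 with an estimated correlation, and 0.065 for the latter with the block). Of the 29, 18 also stand in the immediate-early or effector lists. Of 14 MAP kinase feedback regulators 3 rose and 11 did not pass, 6 adjusted over the list alone and 5 with the block, among them Errfi1, Gem and Dusp4 at 1.42. Their median was 0.77 (adjusted p = 1.45e-13, adjusted p = 0.0474 with an estimated correlation, and 0.115 for the latter with the block). Without wild-type saline replicate 2 this median was 0.51. Several of the MAP kinase regulators, Errfi1 and Dusp4 among them, also stand in the effector list, so these lists are not independent.

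Neuropeptides and granins shifted by a median of 0.20 over 20 genes (adjusted p = 1.61e-05, and adjusted p = 0.0262 with an estimated correlation, which was 0.065 with the block). No member passed over all genes, and 2 did adjusted over the list alone. These 2 were the granin Scg2 at 1.16 (SE 0.23) and neurotensin Nts at 0.83 (SE 0.21). Enkephalin precursor Penk did not pass (0.97, SE 0.48). Penk, also a gene of the striatum, was at log2 11.72 on wild-type kainate replicate 2 and 9.86 on replicate 1, and that replicate 2 had the highest striatum score of the 10 arrays (1.24). Cytokines and chemokines had a median of 0.68 over 10 genes (adjusted p = 6.38e-05, but adjusted p = 0.129 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, changed by 1.62 (SE 0.35) and was the 1 member past the threshold adjusted over the list alone, with 0 over all genes. Growth factors had a median of 0.10 over 9 genes (adjusted p = 0.00419, adjusted p = 0.218 with an estimated correlation), with Bdnf the 1 member that rose and 2 adjusted over the list alone. Heat shock and stress genes had a median of 0.19 over 17 genes (adjusted p = 0.00141, adjusted p = 0.0561 with an estimated correlation), and 0 members passed either way, Dnajb1 being at 0.80. Without wild-type kainate replicate 1 the calls on growth factors (adjusted p = 0.0832) and heat shock genes (0.0587) were lost. While the calls stood, medians moved to 0.27 for cytokines, 0.33 for neuropeptides and 0.0533 for growth factors without wild-type saline replicate 1, and growth factors to 0.28 without its replicate 2. Without wild-type kainate replicate 2 they were 0.15 for growth factors and 0.36 for heat shock genes.

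**Figure D1:**
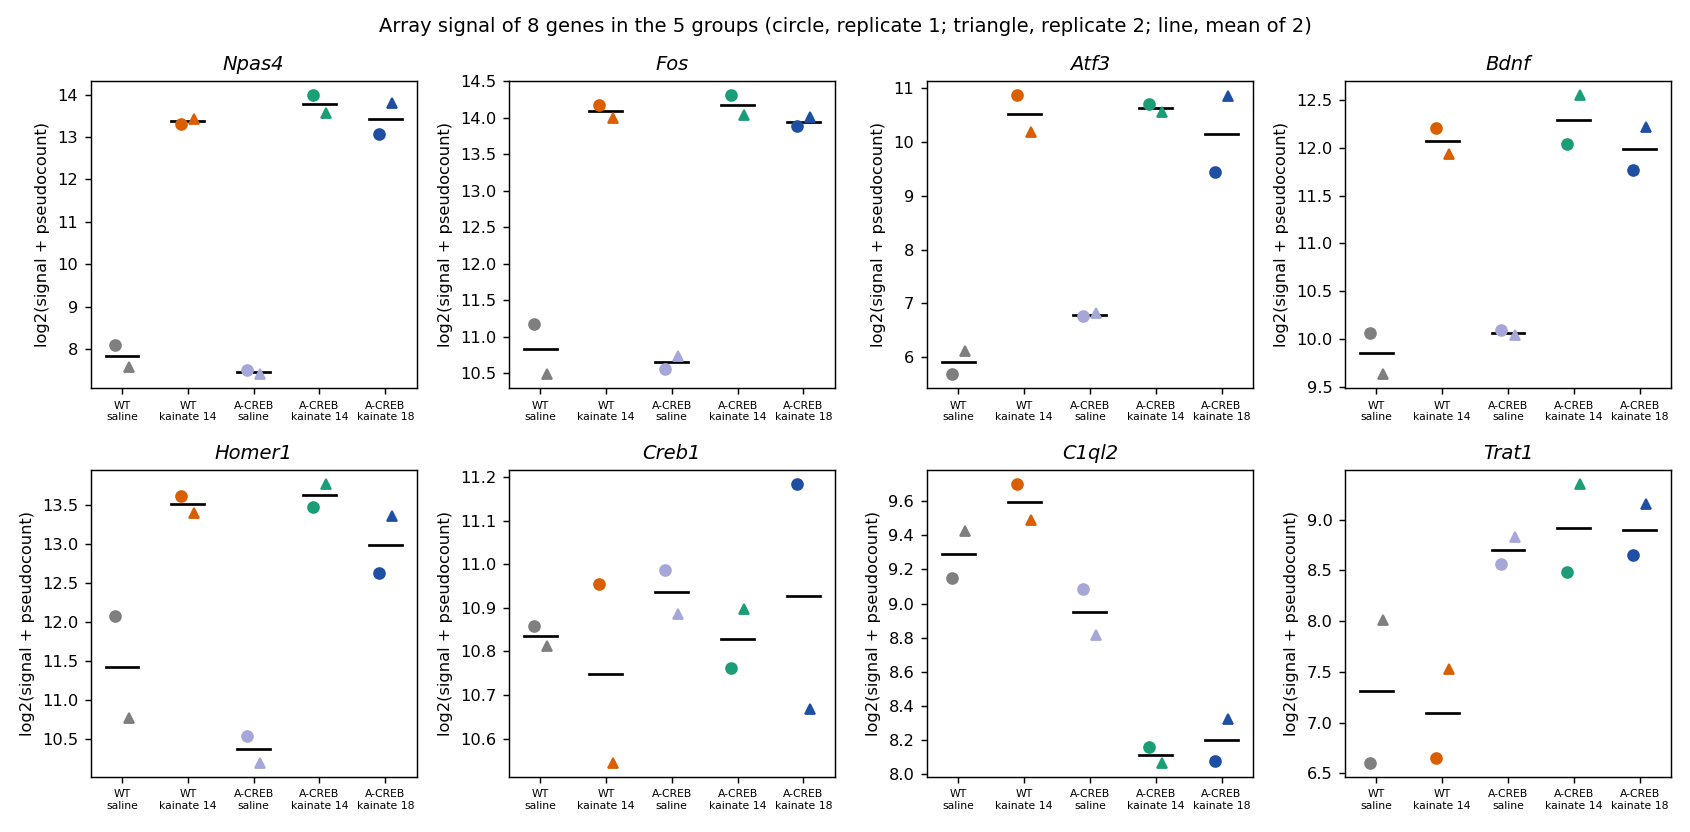
Log2 of the deposited signal plus 22 for 8 genes in the 5 groups, with a circle for replicate 1, a triangle for replicate 2 and a line at the mean of the 2 arrays. Npas4, Fos, Atf3, Bdnf and Homer1 (by its brightest probe set) are higher in the kainate groups of both genotypes, while C1ql2 is lower and Trat1 higher in the A-CREB kainate arrays than in the wild-type kainate arrays.

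A-CREB mice given the same dose answered with the same kind of genes. Npas4 rose 80.2-fold (log2 6.32, SE 0.27, adjusted p = 7.81e-06), from a deposited signal of 154 ± 8.66 (SD, n = 2) to 14224 ± 2905. Fos rose by 3.52 (SE 0.22, adjusted p = 0.000169) and Fosb by 4.58 (SE 0.41, adjusted p = 0.00224). Inhba, which encodes a subunit of activin, rose by 3.65 (SE 0.51, adjusted p = 0.0156), and Homer1, a postsynaptic scaffold gene, by 3.26 by its brightest probe set (SE 0.38, adjusted p = 0.00656). The probe sets of Homer1 disagreed, with 1425671_at at 3.16 and the other 4 from -0.04 to 0.88, and by their mean Homer1 was at 1.23 (adjusted p = 0.327) and lost the call. Atf3 rose by 3.83, the transcription factor Egr2 by 3.43, Ptgs2 by 3.38, the secreted matrix protein gene Ccn1 by 3.30 and Gadd45g by 3.02. Next came the immediate-early gene Ier2 by 2.77, Gadd45b by 2.74, Gem by 2.61 and the transcriptional repressor gene Nfil3 by 2.56. In all, 41 genes rose and 0 fell by limma, with 660 at an unadjusted p under 0.05, and with the replicate block 145 rose and 22 fell, with 1560 at an unadjusted p under 0.05. The count was 19 without A-CREB saline replicate 1, 8 without A-CREB saline replicate 2, 10 without A-CREB kainate 14 mg/kg replicate 1 and 15 without its replicate 2. Npas4, Fos and Fosb passed whichever array was left out, again in fits without the block. Of the 14 genes named, 11 missed the threshold without A-CREB saline replicate 2 (adjusted p from 0.0524 to 0.251), 10 without A-CREB kainate 14 mg/kg replicate 1 (0.0584 to 0.408). Without its replicate 2 there were 7 (0.0622 to 0.230) and 6 without A-CREB saline replicate 1 (0.0639 to 0.225). Ier2 also missed it without wild-type kainate replicate 1 (0.0667) or 2 (0.0584), and Nfil3 without wild-type saline replicate 1 (0.0585) or 2 (0.0510). With all arrays, 6 of the 14 missed it without an intensity trend (0.0524 to 0.153) and Ier2 and Nfil3 with no filter (highest 0.0900). Without _s_at, _x_at and _a_at probe sets Ccn1 was at 2.10 (adjusted p = 0.144).

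Immediate-early transcription factors had a median change of 2.16 in A-CREB mice at 14 mg/kg, with 14 of 25 risen and 11 not passing, 23 adjusted over the list alone and 21 with the block (adjusted p = 2.51e-69, adjusted p = 0.0138 with an estimated correlation). Of the 36 activity-regulated effectors 12 rose and 24 did not pass, 30 adjusted over the list alone and 26 with the block (median 1.53, adjusted p = 1.04e-67, adjusted p = 0.0138 with an estimated correlation, and 0.052 for the latter with the block). They included Ptgs2, Errfi1 at 2.45, Rgs2 at 2.38 and Bdnf at 2.23. Of the 29 CREB target genes 9 rose and 20 did not pass, 19 adjusted over the list alone and 18 with the block (median 1.58, adjusted p = 1.1e-44, adjusted p = 0.0138 with an estimated correlation). MAP kinase feedback regulators gave 4 risen and 10 not passing, 8 adjusted over the list alone and 7 with the block, among them the phosphatase genes Dusp1 at 2.14 and Dusp4 at 1.49. Their median was 1.01 (adjusted p = 3.38e-13, adjusted p = 0.0418 with an estimated correlation, and 0.0965 for the latter with the block). Heat shock and stress genes shifted by a median of 0.55 (adjusted p = 5.27e-08, adjusted p = 0.0138 with an estimated correlation), with 0 members over all genes, 2 adjusted over the list alone and 3 with the block. The chaperone genes Dnajb1 and Hspa5 were at 1.31 and 0.78. Neuropeptides and granins shifted by a median of 0.25 (adjusted p = 1.64e-05, adjusted p = 0.0236 with an estimated correlation, and 0.052 for the latter with the block). They had 0 members over all genes and 4 adjusted over the list alone: Scg2 at 1.21, corticotropin-releasing hormone Crh at 1.92 (SE 0.42), Nts at 0.90 and prepronociceptin Pnoc at 0.92. Growth factors (median 0.37, adjusted p = 1.06e-05, adjusted p = 0.0625 with an estimated correlation) had 2 members risen and 3 adjusted over the list alone. Among cytokines and chemokines (median 0.68, adjusted p = 1.64e-05, adjusted p = 0.0848 with an estimated correlation) Socs3 rose by 2.18 (SE 0.35). While the calls stood, medians moved to 0.39 for cytokines and 0.27 for heat shock genes without A-CREB saline replicate 1, and to 0.15 for neuropeptides without its replicate 2. For growth factors they were 0.18 and 0.19 without A-CREB kainate 14 mg/kg replicate 1 and 2.

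Cell type, glial and immune lists were also shifted in this comparison, all but the dentate granule cell markers by the preset test alone. Dentate granule cell markers shifted by a median of -0.28 over 12 genes (adjusted p = 0.000757, adjusted p = 0.0486 with an estimated correlation, and 0.0676 for the latter with the block). No member passed over all genes and 2 did adjusted over the list alone, the metabolic enzyme gene Tdo2 at -0.93 (SE 0.22) and the secreted synaptic protein gene C1ql2 at -0.84 (SE 0.21). The call was lost without A-CREB kainate 14 mg/kg replicate 1 (median -0.09, adjusted p = 0.0524). Choroid plexus markers had a median of 0.58 (adjusted p = 9.49e-06, adjusted p = 0.292 with an estimated correlation), and 0.37 without A-CREB saline replicate 2 (adjusted p = 0.0615). Microglia markers had a median of 0.22 (adjusted p = 0.012, adjusted p = 0.435 with an estimated correlation), and MHC and interferon genes 0.20 (adjusted p = 0.00399, and 0.435 as adjusted p with an estimated correlation). Both were lost without A-CREB kainate 14 mg/kg replicate 1 (adjusted p = 0.899 and 0.370) and without A-CREB saline replicate 1 (0.446 and 0.719). Reactive astrocyte genes had a median of 0.27 (adjusted p = 0.0205, adjusted p = 0.262 with an estimated correlation), lost without A-CREB saline replicate 1 (0.469) or A-CREB kainate 14 mg/kg replicate 2 (0.128). Without A-CREB saline replicate 2 the medians were 0.64 for reactive astrocyte and 0.39 for MHC and interferon genes. Without A-CREB kainate 14 mg/kg replicate 2 they were -0.45 for dentate markers, 0.44 for microglia and 0.32 for MHC and interferon genes.

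At 18 mg/kg, A-CREB mice again showed Npas4 as the most changed gene, with a 62.9-fold rise (log2 5.97, SE 0.27, adjusted p = 1.35e-05) and a deposited signal of 11410 ± 4078 (SD, n = 2). Fos rose by 3.30 (SE 0.22, adjusted p = 0.000316), Fosb by 4.03 (SE 0.41, adjusted p = 0.00945), Atf3 by 3.36 (SE 0.41, adjusted p = 0.0121) and Ptgs2 by 2.93 (SE 0.35, adjusted p = 0.0121). Ccn1 rose by 3.29, Inhba by 3.12, Gadd45g by 3.10, the antiproliferative gene Btg2 by 2.90, Ier2 by 2.86, Homer1 by 2.63 by its brightest probe set, Gem by 2.47, Gadd45b by 2.46 and Dusp1 by 2.28. In all, 31 genes rose and 0 fell by limma, with 369 at an unadjusted p under 0.05, and with the block 89 rose and 3 fell, with 1183 at an unadjusted p under 0.05. The count was 2 without A-CREB saline replicate 1 and 2 without its replicate 2, 8 without A-CREB kainate 18 mg/kg replicate 2. It was 18 without A-CREB kainate 14 mg/kg replicate 1 and 20 without its replicate 2, and 18 without wild-type kainate replicate 1 or 2. Npas4 and Fos passed whichever array was left out, again in fits without the block. Of the 14 genes named, 12 missed the threshold without A-CREB saline replicate 1 (adjusted p from 0.0652 to 0.504), 12 without its replicate 2 (0.112 to 0.289) and 8 without A-CREB kainate 18 mg/kg replicate 2 (0.110 to 0.567). Among the rest, 6 missed it without wild-type kainate replicate 1 (highest adjusted p 0.0953) and 6 without its replicate 2 (0.0833), 4 without A-CREB kainate 14 mg/kg replicate 1 (0.0685) and 2 without its replicate 2 (0.0626). There were 3 without wild-type saline replicate 1 (0.0628) or 2 (0.0557), and 2 without A-CREB kainate 18 mg/kg replicate 1 (0.0636). With all arrays, 12 of the 14 missed it without an intensity trend (0.0627 to 0.209) and 5 with no filter (0.0502 to 0.0838). By the mean of its probe sets Homer1 was at 0.86 (SE 0.31) and lost the call (adjusted p = 0.9998). As at 14 mg/kg its probe sets disagreed, with 1425671_at at 2.57, near the brightest, and the others from -0.39 to 0.49. Inhba and Btg2 missed it with either other normalization (highest 0.0588).

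Most groups that rose at 14 mg/kg were also shifted at 18 mg/kg in A-CREB mice. Both responses were taken against the same A-CREB saline arrays, so they are not independent. Choroid plexus, reactive astrocyte and oligodendrocyte lists, which passed the preset test at 14 mg/kg, did not pass at 18 mg/kg. Immediate-early transcription factors had a median of 1.90, with 11 risen and 14 not passing, 22 adjusted over the list alone and 20 with the block (adjusted p = 2.36e-67, adjusted p = 0.0189 with an estimated correlation, and 0.0534 for the latter with the block). Activity-regulated effectors had a median of 1.32, with 11 risen and 25 not passing, 26 adjusted over the list alone and 20 with the block (adjusted p = 1.25e-55, adjusted p = 0.0214 with an estimated correlation, and 0.0808 for the latter with the block). Among them were Errfi1 at 2.16 and Bdnf at 1.92. CREB target genes had a median of 1.32, with 8 risen and 21 not passing, 17 adjusted over the list alone and 17 with the block (adjusted p = 2.58e-39, adjusted p = 0.0189 with an estimated correlation, and 0.0534 with the block). MAP kinase feedback regulators had a median of 0.74, with 3 risen and 6 adjusted over the list alone (adjusted p = 4.87e-11, adjusted p = 0.0594 with an estimated correlation). Heat shock and stress genes had a median of 0.39 (adjusted p = 4.04e-07, adjusted p = 0.02 with an estimated correlation, and 0.0534 with the block). There were 0 risen, 1 adjusted over the list alone and 2 with the block, Dnajb1 at 1.41 and Hspa1a at 1.53. Neuropeptides and granins had a median of 0.20 (adjusted p = 0.00021, adjusted p = 0.0389 with an estimated correlation, and 0.0808 with the block), with 0 risen and 3 adjusted over the list alone, among them Crh at 1.94, Scg2 at 0.98 and Nts at 0.84. That call was lost without A-CREB saline replicate 2 (adjusted p = 0.0987). By the preset test alone, growth factors had a median of 0.30 (adjusted p = 4.01e-06, adjusted p = 0.0594 with an estimated correlation) and cytokines 0.45 (0.000214 and 0.132). The cytokine median was 0.19 without A-CREB saline replicate 1, 0.88 without its replicate 2 and 0.68 without A-CREB kainate 18 mg/kg replicate 1, and that of growth factors 0.19 without A-CREB kainate 18 mg/kg replicate 2.

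Cell type and immune lists were shifted at 18 mg/kg by the preset test alone. Dentate granule cell markers had a median of -0.20 (adjusted p = 0.00258, adjusted p = 0.0594 with an estimated correlation), lost without A-CREB kainate 18 mg/kg replicate 1 (0.0787). Microglia markers had a median of 0.22 (adjusted p = 0.00258, adjusted p = 0.418 with an estimated correlation), lost without A-CREB saline replicate 1 (0.249). MHC and interferon genes had a median of 0.14 (adjusted p = 0.0471, adjusted p = 0.627 with an estimated correlation), and -0.02 without A-CREB saline replicate 1 (0.874). This call was also lost without wild-type saline replicate 1 (0.0505) or 2 (0.0507) and A-CREB kainate 18 mg/kg replicate 1 (0.0955) or 2 (0.189). Without A-CREB saline replicate 2 the medians were 0.43 for microglia and 0.29 for MHC and interferon genes.

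Most genes that rose in wild-type mice also rose in A-CREB mice. Of the 24 genes that rose in wild-type mice 23 also rose in A-CREB mice at 14 mg/kg, the exception being Rasl11a. These 23 were among 41 that rose in A-CREB mice. By chance 0.0744 would be shared (exact one-sided hypergeometric p = 2.08e-60, across genes that are not independent). That p also treats the calls as independent, but both comparisons came from 1 fit with a shared spread per gene. With the block 74 of 82 were shared against 0.899 by chance, among 145 that rose in A-CREB mice. Of the 24, 19 also rose in A-CREB mice at 18 mg/kg, against 0.0563 by chance, and Dusp4, Egr4, Nr4a2, Rasl11a and 1700086L19Rik did not pass there. Response size was compared over the 92 genes that passed on the average of both responses at 14 mg/kg, a choice that favours neither genotype there. At 18 mg/kg it favours the wild-type response, since the arrays at 18 mg/kg took no part in it. The mean response was 1.56 ± 0.05 (SD, n = 2 array pairs) in wild-type mice, 1.84 ± 0.02 in A-CREB mice at 14 mg/kg and 1.57 ± 0.43 in A-CREB mice at 18 mg/kg. By exact permutation against wild type the two-sided p was 0.333 at 14 mg/kg, the smallest possible with 2 values against 2, and 1 at 18 mg/kg. The slope of the A-CREB response on the wild-type response was 1.14 at 14 mg/kg (1.16 and 1.07 in the replicates) and 0.99 at 18 mg/kg (0.81 and 1.12). At 14 mg/kg it was below 1 without wild-type saline replicate 1 (0.958, and 0.930 with the block), and with the block also without wild-type kainate replicate 2 (0.995). Over the immediate-early transcription factors the slopes were 1.12 and 1.005, and over the effectors 1.16 and 1.01.

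**Figure D2:**
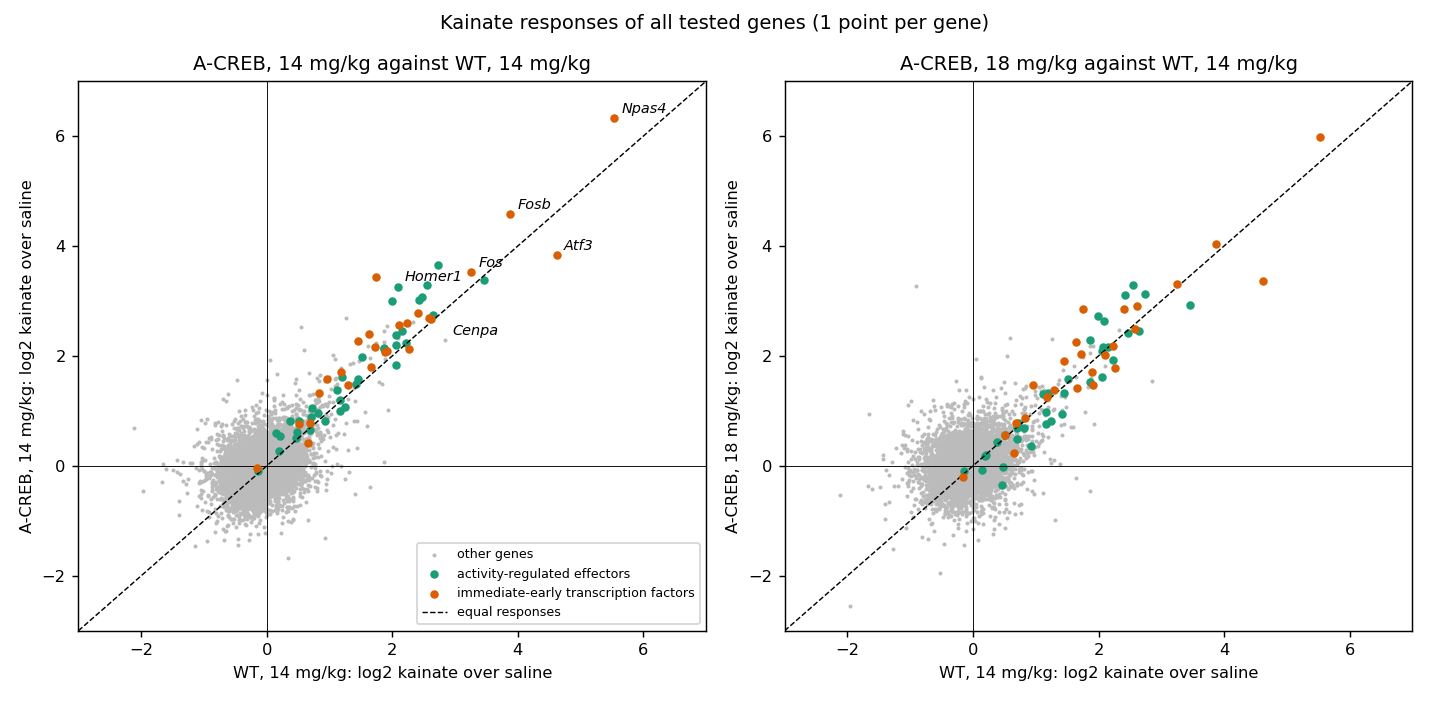
Kainate response (log2 change from saline of the same genotype, means of 2 arrays) of A-CREB mice at 14 mg/kg in the left panel and at 18 mg/kg in the right panel against the response of wild-type mice at 14 mg/kg, for all 13219 tested genes. Immediate-early transcription factors (orange) and effectors (green) lie along the dashed line of equal response, with slopes of 1.12 and 1.16 at 14 mg/kg.

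The difference between the genotypes in the response itself was tested as an interaction, and by limma 0 genes passed at 14 mg/kg. At an unadjusted p under 0.05 there were 96 against 661 expected by chance (0 and 473 with the block). A count so far below the chance figure marks a test that finds little, so 0 genes does not show equal responses. The spread without the block also held the difference between the replicate numbers. By smallest p in their lists, C1ql2 was at -1.14 (SE 0.29, adjusted over the list alone 0.037), Crh at 1.87 (SE 0.60) and Ifit2, an interferon-induced gene, at 1.11. Npas4 was at 0.79 (SE 0.38) and Egr2 at 1.69 (SE 0.70), and none of these passed over all genes. Of 28 lists tested, 12 passed with the preset correlation and 0 with an estimated correlation, where the adjusted p ran from 0.304 to 0.657. Immediate-early transcription factors had a median difference of 0.27 (adjusted p = 0.000945, adjusted p = 0.576 with an estimated correlation) and effectors 0.22 (adjusted p = 0.00613, adjusted p = 0.657 with an estimated correlation). Both calls were lost without wild-type saline replicate 1 (adjusted p = 0.614 and 0.883), wild-type kainate replicate 2 (0.0756 and 0.253) and A-CREB kainate 14 mg/kg replicate 1 (0.114 and 0.0596), and that on the effectors without A-CREB saline replicate 2 (0.263). The first median was 0.67 without wild-type saline replicate 2, 0.52 without A-CREB saline replicate 1 and 0.44 without A-CREB kainate 14 mg/kg replicate 2. Between A-CREB at 18 mg/kg and wild type at 14 mg/kg 0 genes passed (105 at an unadjusted p under 0.05, and 0 and 550 with the block).

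Basal expression was compared between A-CREB and wild-type mice after saline, where 0 of 13219 genes passed by limma. At an unadjusted p under 0.05 there were 195 against 661 expected by chance (0 and 741 with the block). Choroid plexus markers, from the tissue that secretes cerebrospinal fluid, had a median of -0.73 over 10 genes (adjusted p = 3.04e-10, adjusted p = 0.362 with an estimated correlation). No member passed over all genes and 4 did adjusted over the list alone, namely the folate receptor gene Folr1 at -0.99 (SE 0.28), Clic6 at -0.94, the tight junction gene Cldn2 at -1.07 and Slc4a5 at -1.11. Its mean score differed by -0.25 between the arrays numbered 1 and by -1.14 between those numbered 2, and the median was -1.14 without wild-type saline replicate 1 and -0.45 without its replicate 2. Microglia markers had a median of 0.31 (adjusted p = 5.45e-06, adjusted p = 0.362 with an estimated correlation), with Trem2, a microglial receptor gene, at 1.40 (SE 0.66). The call was lost without wild-type saline replicate 2 (median 0.15, adjusted p = 0.152), and the median was 0.18 without A-CREB saline replicate 2. Reactive astrocyte genes had a median of 0.25 (adjusted p = 0.000106, adjusted p = 0.362 with an estimated correlation), and -0.06 without A-CREB saline replicate 2 (adjusted p = 0.190). Without wild-type saline replicate 1 or 2 it was 0.11 or 0.42, and without A-CREB saline replicate 1 it was 0.44. MHC and interferon genes had a median of 0.22 (adjusted p = 0.013, adjusted p = 0.587 with an estimated correlation), with B2m, the light chain of MHC class I, at 0.45. They lost the call without wild-type saline replicate 2 (adjusted p = 0.284) or A-CREB saline replicate 2 (0.965), and the median was 0.36 without A-CREB saline replicate 1. Blood cell markers were too few to test as a list, and neither Slc4a1 at 0.998 (SE 0.36) nor Alas2 at 0.85 (SE 0.43) passed. Their score was 0.30 and 0.95 on the A-CREB saline arrays and -0.50 and -0.09 on the wild-type saline arrays, but at 14 mg/kg the genotypes differed both ways (0.33 against -0.28 in number 1 and -0.41 against -0.02 in number 2). No microglia, reactive astrocyte or MHC member passed over all genes. The activity-regulated gene Egr1 was at -0.58, and its lists did not pass.

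Among mice given 14 mg/kg kainate, A-CREB arrays had higher microglia markers than wild-type arrays, with a median of 0.49 and all 15 members positive (adjusted p = 2.64e-14, but adjusted p = 0.114 with an estimated correlation). By smallest p these were Aif1, the gene of the microglial protein Iba1, at 0.92 (SE 0.30), Laptm5 at 0.66, the growth factor receptor gene Csf1r at 0.51 and Fcrls at 0.49. MHC and interferon genes had a median of 0.49 (adjusted p = 8.15e-13, adjusted p = 0.114 with an estimated correlation), with Ifit2 at 1.44 (SE 0.27, the 1 member past the threshold adjusted over the list alone), B2m at 0.54, the MHC class I gene H2-D1 at 0.59 and Ifit3 at 0.74. Reactive astrocyte genes had a median of 0.45 (adjusted p = 1.58e-07, adjusted p = 0.0998 with an estimated correlation), with the chemokine gene Cxcl10 at 1.25, the astrocyte filament gene Gfap at 0.53 and Lcn2 at 0.83. Over all genes 0 members of these 3 lists passed. As lists, they passed with the preset correlation whichever array was left out, but their medians moved. Microglia were at 0.29 without A-CREB kainate 14 mg/kg replicate 1, MHC and interferon genes at 0.32 without wild-type kainate replicate 1 and reactive astrocyte genes at 0.27 without A-CREB kainate 14 mg/kg replicate 2. The MHC and interferon score differed by 0.81 between the arrays numbered 1 and by 0.16 between those numbered 2. Beside them striatum markers had a median of -0.85 (adjusted p = 0.00119, adjusted p = 0.316 with an estimated correlation), which was 0.26 without wild-type kainate replicate 2 (adjusted p = 0.362), -2.10 without its replicate 1 and -0.52 without A-CREB kainate 14 mg/kg replicate 1 (0.116). Dentate granule cell markers had a median of -0.21 (adjusted p = 9.63e-05, adjusted p = 0.0998 with an estimated correlation), with C1ql2 the 1 member past the threshold adjusted over the list alone, and -0.08 without A-CREB kainate 14 mg/kg replicate 1 (adjusted p = 0.0905). Without its replicate 2 they were at -0.39, and without wild-type kainate replicate 1 at -0.48. Immediate-early transcription factors were at 0.21 (adjusted p = 2.39e-05, adjusted p = 0.325 with an estimated correlation), and without A-CREB kainate 14 mg/kg replicate 1 at 0.13 (adjusted p = 0.0905). Effectors were at 0.12 (adjusted p = 0.00168, adjusted p = 0.491 with an estimated correlation), lost without wild-type kainate replicate 2 (0.363) or A-CREB kainate 14 mg/kg replicate 1 (0.0618), and at 0.23 without wild-type kainate replicate 1. No gene passed by limma, with 168 at an unadjusted p under 0.05, and with the block 5 did, with 658 at an unadjusted p under 0.05. These 5 were chosen after their values were seen: C1ql2 at -1.48 (SE 0.19, adjusted p = 0.0165 with the block), Doc2b, a calcium sensor of synaptic vesicles, at -1.21 (SE 0.17), Trat1 at 1.83 (SE 0.25), Iigp1, an interferon-induced GTPase gene, at 1.33 (SE 0.20) and Pmf1, higher in A-CREB. No fold is given for Pmf1, since its signals on the wild-type kainate arrays, 13.9 and 41.9, lay about the pseudocount. The count with the block was 0 without either A-CREB kainate 14 mg/kg array, 2 without wild-type kainate replicate 2, 9 without either A-CREB saline array and 18 without wild-type kainate replicate 1. The deposited signal of C1ql2 was 754 ± 81.0 (SD, n = 2) in wild-type and 255 ± 12.3 in A-CREB arrays after kainate.

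A-CREB arrays at 18 mg/kg were also compared with wild-type arrays at 14 mg/kg, across different doses. The wild-type arrays were the same as in the comparison at 14 mg/kg, so likeness between these comparisons is not independent support. Effectors had a median of -0.19 (adjusted p = 0.00485, adjusted p = 0.50 with an estimated correlation), opposite in sign to that at 14 mg/kg, and CREB target genes of -0.20 (adjusted p = 0.0333, adjusted p = 0.494 with an estimated correlation). Without A-CREB kainate 18 mg/kg replicate 1 they were at 0.13 (adjusted p = 0.0310) and 0.15 (0.205), and without its replicate 2 at -0.45 and -0.44. Both calls were lost without wild-type kainate replicate 1 (0.327 and 0.283), and that on CREB target genes without A-CREB kainate 14 mg/kg replicate 1 (0.0547) or 2 (0.0544). Microglia markers had a median of 0.50 (adjusted p = 1.69e-13, adjusted p = 0.189 with an estimated correlation), with Aif1 at 0.99, Fcrls at 0.69 and Csf1r at 0.62. MHC and interferon genes had a median of 0.45 (adjusted p = 1.43e-08, adjusted p = 0.203 with an estimated correlation), with Ifit2 at 1.06. Both passed with the preset correlation whichever array was left out, with MHC and interferon genes at 0.29 without wild-type kainate replicate 1. Reactive astrocyte genes had a median of 0.28 (adjusted p = 0.00229, adjusted p = 0.189 with an estimated correlation), lost without wild-type kainate replicate 1 (adjusted p = 0.0604) or A-CREB kainate 18 mg/kg replicate 2 (0.454), and at 0.51 without its replicate 1. Beside them striatum markers had a median of -0.98 (adjusted p = 0.000581, adjusted p = 0.282 with an estimated correlation), 0.20 without wild-type kainate replicate 2 (adjusted p = 0.718), -1.99 without its replicate 1 and -0.59 without A-CREB kainate 18 mg/kg replicate 1 (0.0816). Choroid plexus markers had a median of -0.61 (adjusted p = 2.28e-08, adjusted p = 0.241 with an estimated correlation), -0.15 without A-CREB kainate 18 mg/kg replicate 2 (adjusted p = 0.220) and -0.99 without its replicate 1. No gene passed by limma, with 215 at an unadjusted p under 0.05, and with the block 5 did, with 808 at an unadjusted p under 0.05. These 5 were chosen after their values were seen: C1ql2 at -1.39, Ccdc80 at 1.40 (SE 0.18), Cenpa at -1.23 (SE 0.17) and Trat1 at 1.81, each with an adjusted p of 0.0158 with the block. The other was Clec7a, a receptor gene of myeloid cells, at 1.95 (SE 0.31, adjusted p = 0.0475 with the block). The count with the block was 0 without wild-type kainate replicate 2, A-CREB kainate 18 mg/kg replicate 2 or either A-CREB kainate 14 mg/kg array, and 12 without wild-type kainate replicate 1.

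**Figure D3:**
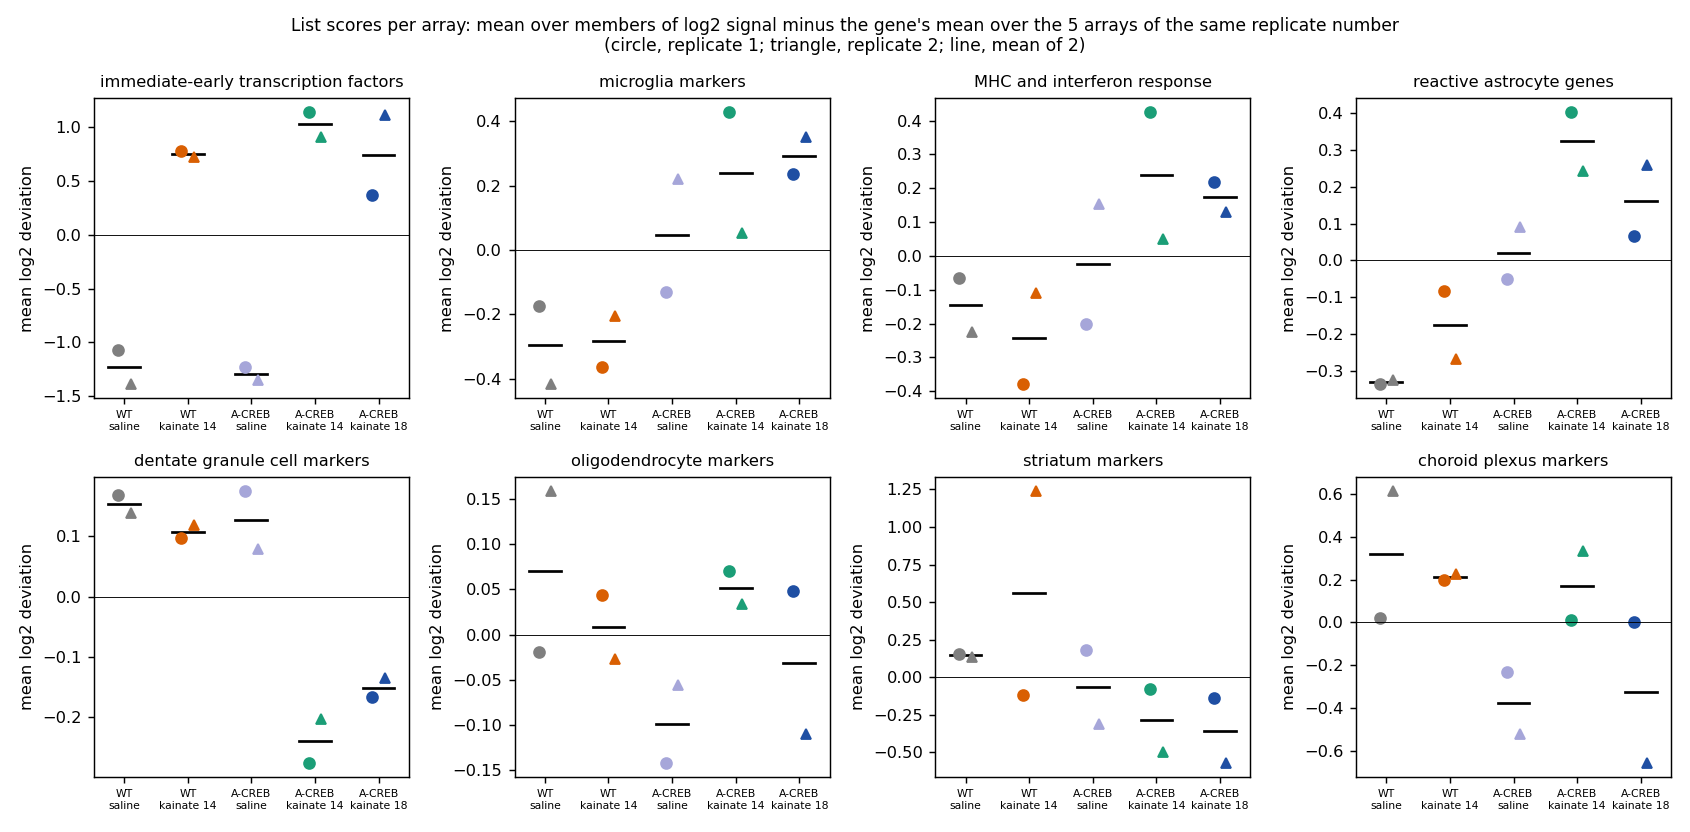
Mean over a list's members of log2 signal minus the gene's mean over the 5 arrays of the same replicate number, for 8 gene lists on each array, with the groups along the x axis, a circle for replicate 1 and a triangle for replicate 2. The immediate-early transcription factors are higher on the kainate arrays of both genotypes, and the striatum score of wild-type kainate replicate 2 is 1.24.

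Between the doses, A-CREB mice at 18 mg/kg had lower immediate-early transcription factors than at 14 mg/kg by the preset test, with a median of -0.35 (adjusted p = 7.38e-10, but adjusted p = 0.297 with an estimated correlation). Effectors were at -0.28 (adjusted p = 4.59e-14, adjusted p = 0.297 with an estimated correlation) and CREB target genes at -0.23 (adjusted p = 4.86e-06, adjusted p = 0.297 with an estimated correlation). All 3 calls rested on A-CREB kainate 18 mg/kg replicate 1, without which the medians were 0.06 (adjusted p = 0.749), -0.00 (0.894) and -0.01 (0.890). Without its replicate 2 they were -0.66, -0.66 and -0.50. By smallest p, Egr4, an immediate-early transcription factor, was at -0.62 and Dusp4 at -0.56. Choroid plexus markers were at -0.53 (adjusted p = 6.89e-11, adjusted p = 0.297 with an estimated correlation), at -0.12 without A-CREB kainate 18 mg/kg replicate 2 (adjusted p = 0.335) and at -0.98 without its replicate 1. No gene passed by limma, with 75 at an unadjusted p under 0.05 against 661 expected by chance, and 0 and 400 with the block.

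Creb1, the gene of CREB itself, was read by 6 probe sets, compared over the 6 A-CREB and 4 wild-type arrays. Probe set 1423402_at was higher in A-CREB by 0.57 (exact permutation within replicate numbers, two-sided p = 0.01, adjusted p = 0.06 over the 6), with every A-CREB array (signals of 199 to 281) above every wild-type array (116 to 193). Probe set 1452529_a_at differed by 1.02 (exact permutation adjusted p = 0.06), and the brightest, 1452901_at, by 0.10 (exact permutation adjusted p = 0.465), with a signal of 1806 ± 42.0 (SD, n = 2) in wild-type saline and 1939 ± 94.5 in A-CREB saline. Of the other 3, 1421583_at lay below the filter (signals of 2.04 to 65.5) but was counted in the adjustment over 6, and 2 were at -0.11 and 0.07, with a lowest exact permutation adjusted p of 0.708. The smallest p that the 100 arrangements can give is 0.01.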

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

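The tests on same-numbered pairs, on striatum and choroid plexus scores, on RNA ratios, on lists between replicate numbers and on Creb1 were chosen after the results were seen, and the 2 counts over other splits of the arrays were planned.

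In 12 lists the response to 14 mg/kg kainate differed between the genotypes by camera with the preset correlation, which is why they stand here, and none did with an estimated correlation. Choroid plexus markers differed by a median of 0.80 (adjusted p = 3.51e-06, adjusted p = 0.576 with an estimated correlation), thalamus markers by 0.57 (0.0163 and 0.576) and striatum markers by -0.56 (0.0447 and 0.657). Dentate granule cell markers differed by -0.33 (0.00144 and 0.304), heat shock and stress genes by 0.30 (0.0163 and 0.304) and CA pyramidal cell markers by -0.13 (0.0163 and 0.304). Immediate-early transcription factors differed by 0.27 (0.000945 and 0.576), activity-regulated effectors by 0.22 (0.00613 and 0.657) and CREB target genes by 0.21 (0.0163 and 0.602). MHC and interferon genes differed by 0.23 (0.00144 and 0.576), oligodendrocyte markers by 0.23 (0.00613 and 0.576) and microglia markers by 0.18 (0.0427 and 0.657, and 0.0528 by the preset test with the replicate block). Of the 12 calls, 11 were lost without A-CREB kainate 14 mg/kg replicate 1 (adjusted p from 0.0508 to 0.734), 10 without wild-type saline replicate 1 (0.0572 to 0.883), 9 without wild-type kainate replicate 2 (0.0756 to 0.253) and 7 without A-CREB saline replicate 1 (0.0711 to 0.579). The other arrays whose loss ended calls were A-CREB saline replicate 2 with 4 calls (0.0726 to 0.524), wild-type kainate replicate 1 with 4 (0.0680 to 0.463), wild-type saline replicate 2 with 3 (0.0640 to 0.149) and A-CREB kainate 14 mg/kg replicate 2 with 1 (0.210). While the call stood, the choroid median was 0.46 without wild-type saline replicate 2 and 0.47 without A-CREB saline replicate 2, and the striatum median -1.12 without wild-type saline replicate 2 and -1.78 without wild-type kainate replicate 1. Without wild-type saline replicate 2 medians were also 0.67 for immediate-early transcription factors, 0.44 for CREB target genes, 0.18 for heat shock genes, 0.41 for MHC and interferon genes and 0.49 for microglia. Without A-CREB kainate 14 mg/kg replicate 2 they were 0.44 for immediate-early transcription factors, 0.51 for MHC and interferon genes, 0.40 for microglia and -0.50 for dentate markers, and without wild-type kainate replicate 1 -0.51 for dentate and -0.21 for CA markers. Without A-CREB saline replicate 2 they were 0.48 for MHC and interferon genes, 0.88 for thalamus and -0.24 for CA markers, without A-CREB saline replicate 1 0.52 for immediate-early transcription factors, and without wild-type kainate replicate 2 0.48 for MHC and interferon genes.

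With A-CREB at 18 mg/kg in place of 14, 5 lists differed in response by the preset test, each with an adjusted p of 0.049, and none with an estimated correlation. They were striatum markers at -0.71, MHC and interferon genes at 0.20 and microglia markers at 0.16 (adjusted p = 0.786 with an estimated correlation for each), and dentate granule cell markers at -0.29 and CA pyramidal cell markers at -0.12 (0.485 for both). With the replicate block only the striatum markers passed the preset test (0.0104, the others from 0.0686 to 0.0733). All 5 calls were lost without wild-type saline replicate 1 (adjusted p from 0.168 to 0.974), A-CREB saline replicate 1 (0.0976 to 0.840) or A-CREB kainate 18 mg/kg replicate 1 (0.0593 to 0.199). Without wild-type kainate replicate 1 there were 4 lost (0.0668 to 0.770), without its replicate 2 also 4 (0.0989 to 0.573), and without A-CREB saline replicate 2 there were 3 (0.0604 to 0.256). Without A-CREB kainate 18 mg/kg replicate 2 there were 3 (0.0542 to 0.0796), and without wild-type saline replicate 2 there was 1 (0.123). While calls stood, medians without wild-type saline replicate 2 were -1.19 for striatum, 0.36 for MHC and interferon genes, 0.43 for microglia and -0.44 for dentate markers. The striatum median was -1.78 without wild-type kainate replicate 1, those of MHC and interferon genes 0.48 without wild-type kainate replicate 2 and 0.44 without A-CREB saline replicate 2, and that of microglia 0.32 without A-CREB saline replicate 2.

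Among probe sets without a gene name, which the gene comparisons did not use, 2 rose in A-CREB mice at 14 mg/kg, 1435137_s_at by 1.25 (SE 0.19) and 1455166_at by 2.14 (SE 0.32), both with a limma adjusted p of 0.0488.

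Microglia and reactive astrocyte scores were higher in A-CREB in 4 of 4 same-numbered pairs, and MHC and interferon scores in 3 of 4 (mean 0.30, SD 0.40, and -0.13 in saline pair 1). These lists were chosen for being higher in A-CREB on the same arrays, so the pair counts add no separate support. Cytokine and apoptosis scores were also higher in every pair, and neuropeptide and circadian clock scores were lower in every pair. Against a lower share of neurons in the A-CREB pools as the whole cause, the microglia difference exceeded the mean of the oligodendrocyte and endothelial differences by 0.51 (SD 0.33, in 4 of 4 same-numbered pairs). But dentate (mean -0.19, SD 0.19), CA pyramidal (-0.10, SD 0.11) and synaptic scores (-0.08, SD 0.18) were each higher in A-CREB in only 1 of 4 pairs. Astrocyte markers were higher in 4 of 4 (0.08, SD 0.08). Not all neuronal lists were lower. Over saline and 14 mg/kg, immature neuron scores were 0.0268 to 0.131 on A-CREB arrays and -0.156 to -0.0846 on wild-type arrays. Interneuron scores differed both ways (-0.0499 in A-CREB against -0.103 in saline pair 1, and -0.0204 against 0.0381 in pair 2 at 14 mg/kg). With 4 pairs no sign-flip p can fall below 0.125, so a lower share of neurons stays open. For striatal or choroid plexus tissue as a cause, the microglia median at 14 mg/kg was 0.60 with both scores as covariates and 0.49 without them. The mean score difference was 0.61 (SE 0.23, 2 residual degrees of freedom) against 0.52 (SE 0.21). It was 0.64 (SE 0.29) against 0.48 for MHC and interferon and 0.40 (SE 0.12) against 0.50 for reactive astrocyte genes. With 2 residual degrees of freedom these differences are too uncertain to exclude such tissue as the whole cause. It stays open in whole or in part (group means of log2 14.62 to 14.94 for choroid Ttr and 9.02 to 10.13 for striatal Ppp1r1b). The microglia list did not pass with an estimated correlation with the scores (adjusted p = 0.552) or without them (0.172 with the block and 0.114 without it). An effect of the A-CREB genotype, as a hypothesis, may account for the mean microglia pair difference of 0.43 (SD 0.34), but the exact sign-flip p of 0.125, two-sided, is the smallest that 4 pairs can give, so it cannot be told apart from differences between pools.

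The replicate numbers separated the arrays, with 4618 genes different between them (2726 higher and 1892 lower in number 2) and median signals of 94.5 to 106 in number 1 and 134 to 152 in number 2. Same-numbered arrays of different groups correlated at 0.961 to 0.986 and the arrays of a group at 0.952 to 0.964. RNA degradation stays open, since the actin 3' to 5' ratio was higher in number 2 in 2 of 5 groups and the Gapdh ratio in 5 of 5. A different tissue outline or cell make-up stays open too, since striatum markers were higher in number 2 by a median of 1.03 with an adjusted p of 0.0769 (0.975 with an estimated correlation). What the numbers mark is not in the labels, so no difference between the mice themselves, such as litter, was tested.

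Some Creb1 probe sets were brighter in A-CREB. Chance among the Creb1 probe sets stays open: with arrays exchanged within replicate numbers the lowest exact permutation adjusted p was 0.06, the smallest that a single probe set can reach, with 6 of 6 A-CREB arrays above every wild-type array for 1423402_at. A transgene transcript read by some Creb1 probe sets is a candidate explanation, since A-CREB carries part of the CREB sequence, and 1 of the 6 probe sets separated the genotypes fully. Which probe sets lie within the transgene is not known here, so a change of the mouse's own Creb1 stays open.

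Over the 8 arrays of saline and 14 mg/kg, with replicate number and the other factor in the model, the real split by treatment gave 398 genes. The highest of the other splits gave 5, and 1 of 33 splits gave as many as the real one. Only 8 of these splits part all 4 pairs of saline and kainate arrays of the same genotype and number. Among those the highest other gave 0. With the pairs kept the share cannot fall below 1 in 8, so this count alone does not exclude chance. The real split by genotype gave 1 gene and the highest other 8, and 8 of 33 splits gave as many, so chance cannot be excluded for that count. Among the 8 splits that part all 4 same-numbered pairs, as the real one does, the highest other also gave 1.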

How the results depend on the processing

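Leaving out arrays within the replicate block, the block with quantile normalization and the block with striatum and choroid plexus scores were tests chosen after the results were seen, and the others were planned.

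All 42 named gene results kept their direction in every setting run. They lost the call in 24 of 42 cases without an intensity trend, in 6 with the mean of a gene's probe sets (Homer1 fell from 3.26 to 1.23 and from 2.63 to 0.86, since its probe sets disagreed, while Gadd45b kept its calls at 1.93, 2.11 and 1.80), in 135 of 420 with 1 array left out, in 0 of 42 with the replicate block and in 2 of 420 with 1 array left out within the block. Of 93 list shifts called, 27 changed sign in at least 1 setting, and lost calls numbered 5 with the replicate block, 14 with quantile normalization, 13 with cyclic loess, 16 with the upper 40%, 11 with no filter and 22 with the block and tissue scores, where 6 more changed sign. With 1 array left out 154 of 930 were lost and 20 changed sign, and within the block 120 and 21. The filter sets how dim a probe set may be over background, and the number of arrays limits all counts. A lone array left in a group was assumed to vary like the others.

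The counts of genes changed in wild type at 14 mg/kg and in A-CREB at 14 and 18 mg/kg moved from 24, 41 and 31 to 94, 167 and 92 with the replicate block, to 85, 159 and 91 with the block and quantile normalization, and to 136, 161 and 109 with the block and the 2 tissue scores. They moved to 9, 21 and 2 without an intensity trend, and that at 18 mg/kg to 20 with no filter and to 20 without _s_at, _x_at and _a_at probe sets. The genotype differences after kainate, 0 and 0 genes, became 5 and 5 with the block, 5 and 3 with quantile normalization added, and 9 and 2 with the scores. With the scores the response difference at 14 mg/kg gave 2 genes and the response size 1.28, over 457 genes. With 1 array left out, in both fits, the counts ran from 5 to 128 in wild type, 8 to 265 and 2 to 183 in A-CREB, 0 to 1 at baseline, 0 to 2 and 0 to 3 for the response differences, 0 to 18 between genotypes at 14 mg/kg and 0 to 12 at 18 against 14 mg/kg. Within the block the lowest 14 mg/kg genotype count, 0, was without either A-CREB kainate 14 mg/kg array and the highest, 18, without wild-type kainate replicate 1. Response size ran from 0.93, without wild-type saline replicate 1 and so below 1, to 1.19, and at 18 mg/kg from 0.71 to 1.17, the latter lowest without A-CREB kainate replicate 2 and highest without its replicate 1. The cause was not tested for these moves.

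With the mean of a gene's probe sets the growth factor median in wild type was -0.0111. With the block and tissue scores, medians turned for choroid plexus markers at baseline (0.0552) and in the response difference (-0.00528) and for striatum markers at 14 mg/kg (0.10), which the scores remove by construction. At 18 against 14 mg/kg between genotypes they turned for synaptic genes (0.0341) and channels (0.0678), and between the doses for oligodendrocyte markers (0.0120), where the cause was not tested.

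List medians that turned when 1 array was left out, in either fit, had these ranges. For baseline they were -0.14 to 0.62 for cytokines, -0.0602 to 0.44 for reactive astrocyte genes and -0.0294 to 0.41 for MHC and interferon genes. In the response of A-CREB at 14 mg/kg they were -0.0243 to 0.44 for MHC and interferon genes, -0.0744 to 0.47 for microglia and -0.45 to 0.0847 for synaptic genes, and at 18 mg/kg -0.0164 to 0.36 for MHC and interferon genes and -0.39 to 0.0522 for synaptic genes. In the response difference at 14 mg/kg they were -1.78 to 0.29 for striatum, -0.14 to 0.49 for microglia and -0.00313 to 0.58 for MHC and interferon genes, and for 18 against 14 mg/kg -1.81 to 0.12 for striatum and -0.0163 to 0.43 for microglia. Between genotypes, striatum ran from -2.10 to 0.26 at 14 mg/kg, and at 18 against 14 mg/kg striatum ran from -1.99 to 0.20, effectors from -0.52 to 0.21, CREB target genes from -0.53 to 0.18 and synaptic genes from -0.23 to 0.0527. Between the doses immediate-early transcription factors ran from -0.83 to 0.13, effectors from -0.73 to 0.0281, CREB target genes from -0.59 to 0.10, MAP kinase regulators from -0.50 to 0.17 and oligodendrocyte markers from -0.19 to 0.0787. The upper ends came without wild-type kainate replicate 2 for striatum and without A-CREB kainate 18 mg/kg replicate 1 for effectors and CREB target genes.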

Other observations

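The genotype difference averaged over saline and 14 mg/kg was a test chosen after the results were seen, and the lists, their tests and the splits were planned.

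Neuronal and glial lists other than those above were shifted between genotypes after kainate by the preset test alone. CA pyramidal cell markers had a median of -0.21 at 14 mg/kg (adjusted p = 0.00488, adjusted p = 0.114 with an estimated correlation), with Fibcd1 at -0.47, and -0.18 at 18 against 14 mg/kg (0.0225 and 0.189). The first was lost without wild-type kainate replicate 2 (0.224) and A-CREB kainate 14 mg/kg replicate 1 (0.0905). The second was lost without wild-type kainate replicate 2 (0.263) and A-CREB kainate 18 mg/kg replicates 1 (0.127) and 2 (0.0669). Immature neuron and neurogenesis markers had a median of 0.21 at 14 mg/kg (0.00676 and 0.114), with Dcx, a microtubule gene of young neurons, at 0.57 (SE 0.42), lost without wild-type kainate replicate 1 (0.198) and A-CREB kainate 14 mg/kg replicate 2 (0.215), and at 0.36 without wild-type kainate replicate 2. Astrocyte markers had a median of 0.13 at 14 mg/kg (0.0125 and 0.114), with the water channel gene Aqp4 at 0.60 (SE 0.19) and Gja1 at 0.33, lost without wild-type kainate replicate 2 (0.292) and A-CREB kainate 14 mg/kg replicate 1 (0.424). Enkephalin precursor Penk was at -1.42 (SE 0.48) and prodynorphin Pdyn at -0.82 at 14 mg/kg, and Penk, also a gene of the striatum, at -1.49 at 18 against 14 mg/kg. Cytokines and chemokines had a median of 0.51 at 14 mg/kg (0.000189 and 0.122), with Cxcl10 at 1.25, lost without A-CREB kainate 14 mg/kg replicate 2 (0.144).

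Within A-CREB mice, synaptic vesicle and scaffold genes had a median of -0.21 at 14 mg/kg (adjusted p = 0.0248, adjusted p = 0.532 with an estimated correlation), with Camk2a, a kinase gene of synaptic plasticity, at -0.32, and -0.19 at 18 mg/kg (0.00604 and 0.508). Both turned to positive without A-CREB saline replicate 1, with medians of 0.08 and 0.05, were -0.45 and -0.39 without its replicate 2, and lost the call without A-CREB kainate 14 mg/kg replicate 2 (0.227) and A-CREB kainate 18 mg/kg replicate 2 (0.201). Voltage-gated channels had a median of -0.14 at 18 mg/kg (0.0171 and 0.312), lost without A-CREB saline replicate 1 (0.428) and either 18 mg/kg array (0.0776 and 0.0708). Oligodendrocyte markers had a median of 0.15 at 14 mg/kg (0.00399 and 0.317) and -0.16 at baseline against wild type (0.00748 and 0.398), the first lost without A-CREB kainate 14 mg/kg replicate 1 (0.0913), the second without wild-type saline replicate 2 (0.198) or A-CREB saline replicate 1 (0.135). Without A-CREB saline replicate 2 these medians were 0.24 and -0.25, and the first was 0.23 without A-CREB kainate 14 mg/kg replicate 2. Crem, a CREB family gene with an inducible repressor form, was at 1.17 (SE 0.26, adjusted over the list alone 0.0131) at 14 mg/kg and 1.08 at 18 mg/kg, and did not pass over all genes. Circadian clock genes were at -0.07 at 18 mg/kg against wild type at 14 mg/kg (0.00771 and 0.189), lost without wild-type kainate replicate 2 (0.117) or A-CREB kainate 18 mg/kg replicate 1 (0.217), and at -0.29 without wild-type kainate replicate 1 and -0.19 without A-CREB kainate 18 mg/kg replicate 2. Apoptosis and survival genes were at -0.13 between the doses (0.0219 and 0.297), lost without any of the 4 arrays of these groups (0.108 to 0.436).

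Of the 28 lists tested, 5 passed in no comparison. Their lowest adjusted p with the preset correlation were 0.0788 for glutamate receptors, 0.116 for the CREB family and coactivators, 0.123 for endothelial and mural markers, 0.151 for interneuron markers and 0.280 for GABA receptors. Blood cell markers, with 2 of 7 genes measured, and sex-linked genes, with 1 of 5, were not tested. Xist was bright in all 5 groups, with means from 4521 to 5343 for probe set 1436936_s_at.

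Averaged over saline and 14 mg/kg (4 arrays against 4), 0 genes differed between the genotypes by limma, with 268 at an unadjusted p under 0.05, and 4 did with the replicate block, with 870 at an unadjusted p under 0.05. These 4 were chosen after their values were seen: Trat1 at 1.61 (SE 0.18, adjusted p = 0.00464 with the block), an adaptor gene of T cells, Doc2b at -0.92 (SE 0.12), C1ql2 at -0.91 (SE 0.14) and Pmf1, higher in A-CREB but with signals about the pseudocount on the wild-type kainate arrays. Over the same 8 arrays alone, with treatment and replicate number in the model, the real split by genotype gave 1 gene and the highest other split 8, with 8 of 33 splits giving as many, so chance cannot be excluded.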
